A study of Mus musculus with 14 samples.

How the data were processed

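RNA of epididymal fat from 14 mice (5 CC, 5 UC, 4 UU) was measured on single-channel Affymetrix arrays. Groups were taken from the group assignment in the labels. The deposited values are intensity signals on a linear scale, made by the authors with GCOS 1.3 and MAS5, per the submitters' processing notes. In the deposited table each array's mean signal after trimming 2% at each end lay between 1500.45 and 1500.57, and the lowest value was 0.2. Detection calls, scan dates, slides and litters were not used here. No 2 arrays were duplicates, with correlations of log2 values within groups from 0.817 to 0.958.

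Of 22690 probe sets, the platform annotation gave 1 gene symbol for 20380, several for 691 and none for 1555, and 64 were control probe sets. Symbols were updated through Entrez identifiers to a RefSeq gene table of the mouse reference assembly for 20351 probe sets and kept for 29. For each of 12393 genes the probe set of highest mean over all 14 arrays was used, and 4956 genes had several. Values were transformed as log2(value + 32), and the dimmest 40% of genes by mean over all arrays were left out, leaving 7436. All 14 arrays entered one linear model in limma 3.58.1 (R 4.3.3, 11 residual degrees of freedom, empirical Bayes with a mean-variance trend) with 3 two-sided contrasts, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. A log2 difference ± SE is limma's coefficient with its moderated standard error, and fold changes were taken from this coefficient. Signals are given as mean ± SD.

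A set of 42 gene lists covering metabolism, adipocyte function, growth, stress, immunity and markers of other cell types was written from general knowledge before the data were examined, as were the design, most of the alternative fits and the rule for naming genes. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 42 lists within each comparison. They were also tested with an estimated correlation, with fry and with an exact permutation of the samples' list scores. Camera called 3 lists in UC against CC, 12 in UU against CC and 17 in UC against UU. With an estimated correlation it called 0 of them, and no exact permutation p of a list passed adjustment (smallest adjusted values 0.167, 0.185 and 0.0952). The smallest exact permutation p was 0.00794 in each comparison, the lowest these group sizes allow. A list could therefore pass adjustment over 42 lists only if several lists reached that value. Named genes were the 8 largest rises and falls among called genes, or the 5 of smallest p where fewer than 5 passed, a fixed panel of 25 metabolic genes, up to 4 members of smallest p in the direction of each called list, and the 2 brightest members of each cell type list where it is discussed. Acaca and Ucp1 of the panel fell below the signal filter. Liver and Y-linked markers were added after the data were seen.

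The fit was tested on simulated arrays with 200 changed genes among 7436. It recovered 73.3% of 2-fold and 96.8% of 4-fold changes for UC against CC, 66.2% and 95.2% for UU against CC, and 66% and 95.7% for UC against UU, with 5.37%, 5.7% and 4.07% of calls false. These arrays were drawn with independent genes, which real arrays do not have. A list shifted by 0.5 on the log2 scale was found in 5 of 5 simulations for each comparison.

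Alternatives covered the pseudocount (1, 128), the filter (none, dimmest 60%), median centring and quantile normalization, the probe set rule, the variance model, array weights, fits of 2 groups only, the replicate number as a block, an adjusted p of 0.1, and each array left out. After seeing the data, fits without the 2 samples with Xist signal, without the 4 low in epididymal markers and without the 3 of highest 3'/5' ratio were added, as were fits with the epididymal marker level, the 3'/5' ratio or both as covariates, and list scores were fitted with the general epithelial score or the liver marker level as a covariate. No sample was left out of the values reported. Figures were drawn with matplotlib 3.10.9.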

Results

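Gene expression was measured on Affymetrix mouse arrays in epididymal fat, a white fat depot, of 14 ICR mice labelled male and 3 weeks old. The CC group (n = 5) came from dams fed ad libitum in pregnancy and lactation. The UC group (n = 5) was exposed to a 50% restriction of the dam's food in utero and nursed by dams fed ad libitum. The UU group (n = 4) had the same restriction in utero and through suckling. Every array had been scaled to the same trimmed mean signal of 1500. After the dimmest 40% of genes were left out, 7436 genes were tested. The series title names accelerated postnatal growth and lipogenic genes, which gives the comparisons of UC with the other groups their purpose. The labels do not say whether mice of a group were littermates, so the p-values treat each array as an independent animal. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.20 for UC against CC and 0.22 for either comparison with UU.

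The arrays differed in the tissues they carried. Gpx5, a glutathione peroxidase of the epididymal epithelium, had signals of 409.6, 828, 857 and 1155 in CC replicates 2 and 4 and UC replicates 2 and 5, and of 5711 to 69624 in the other 10 samples, which include all 4 UU mice. Lcn5, an epididymal lipocalin, was at most 166.5 in the same 4 samples and reached 25325 in CC replicate 1. The mean log2 level of the 10 tested epididymal markers was 10.94 ± 2.36 (SD) in CC, 10.42 ± 1.97 in UC and 11.86 ± 0.54 in UU. Its difference between UC and UU was -1.44 (exact permutation test, two-sided, p = 0.302), and -0.90 without UC replicate 2. Xist, the RNA that silences one X chromosome in females, had signals of 3981 in CC replicate 2 and 5642 in UC replicate 5, against at most 1324 in the other 12, while the Y-linked Eif2s3y was at 58.6 and 7.9 there and at 1235 to 2234 elsewhere. Kdm5d, also Y-linked, was at 150.3 and 339.5, against 716 to 1835. Alb, the albumin transcript made by liver, was at 25660.3 in UC replicate 2 and at 550.4 to 3190.5 in the others. The log2 ratio of 3' over 5' probe set signal of Gapdh and Actb, which rises as RNA is degraded, was 1.63, 1.60 and 2.11 in UC replicates 1 and 4 and UU replicate 3, and 0.40 to 1.08 in the other 11.

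**Figure D1:**
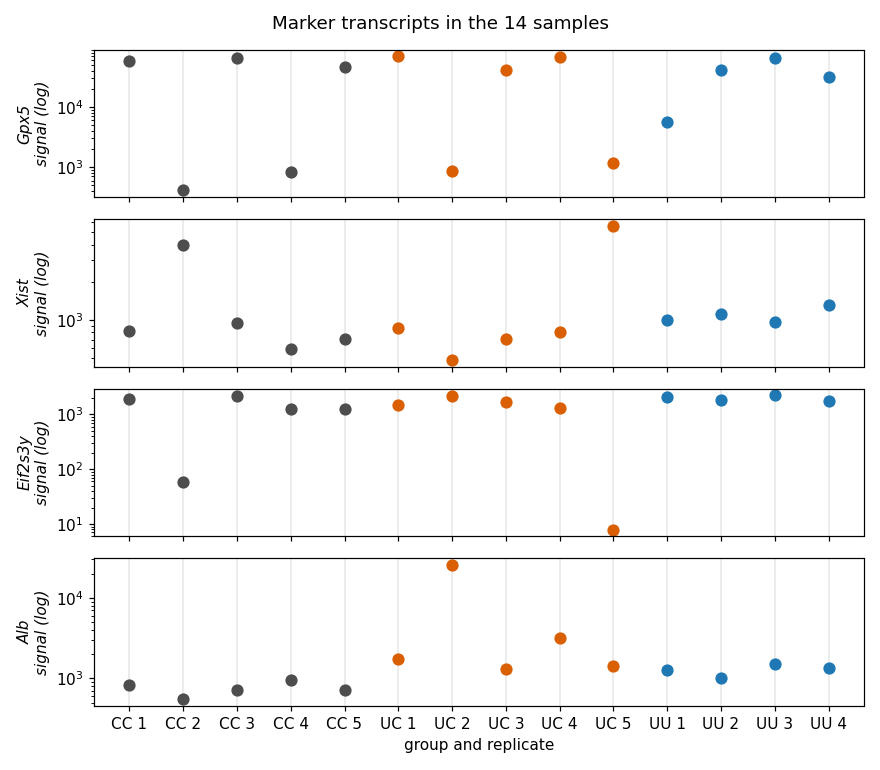
Signal (log axis) of Gpx5, Xist, Eif2s3y and Alb in each of the 14 samples, named by group and replicate, with CC in grey, UC in orange and UU in blue. Gpx5 lies between 409.6 and 1155 in 4 samples, and the Xist signals of 3981 and 5642 belong to 2 of them.

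UC against CC asks how fat differs at weaning after growth restriction in utero followed by ample milk. Transcripts of fatty acid synthesis were higher in UC as a group, and no single gene passed. The de novo lipogenesis list, fixed beforehand, was higher in UC (20 members tested, 15 above and 5 below 0, median log2 difference 0.30, camera adjusted p = 0.000167 over 42 lists, adjusted p = 0.845 with an estimated correlation). Fasn, the fatty acid synthase, had a signal of 41823 ± 11864 in UC and 19941 ± 3192 in CC (SD, n = 5 each), a log2 difference of 1.03 ± 0.31 (SE, limma adjusted p = 0.47), with all 5 UC samples above the highest CC sample. Acss2, which makes acetyl-CoA from acetate, was at 7194 ± 1461 against 2929 ± 1151 (log2 difference 1.34 ± 0.27, adjusted p = 0.381). Pnpla3, a lipid droplet enzyme under lipogenic control, had a log2 difference of 1.38 ± 0.42, and Pgd, an NADPH-producing dehydrogenase of the pentose phosphate pathway, one of 0.69 ± 0.19. No member passed over all 7436 genes, and 5 were higher when adjusted over the list alone. The remaining lipogenic genes of the fixed panel gave log2 differences of 1.06 ± 0.34 for Thrsp, 0.62 ± 0.30 for Srebf1, 0.52 ± 0.28 for Acly, 0.31 ± 0.18 for Scd1, 0.25 ± 0.21 for Elovl6 and 0.26 ± 0.20 for Mlxipl. Gpam and Dgat2, lipid synthesis genes of the same panel, gave -0.06 and 0.47. Dimmer probe sets gave 0.15 for Thrsp, -0.06 for Scd1, -0.75 for Gpam and 0.02 for Dgat2.

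Transcripts of liver, a tissue that makes fatty acids too, also differed between these groups. Their mean log2 level, examined after the data were seen, was 9.56 ± 1.57 (SD) in UC and 8.06 ± 0.26 in CC (exact permutation test, two-sided, p = 0.0238). This mean took in dim markers that fell below the signal filter, such as Fgb, Ahsg, Fga and Hpx. It therefore rests in part on values near the floor. Without UC replicate 2 the UC mean was 8.90 ± 0.65 and the difference 0.85 (exact permutation test, two-sided, p = 0.0238). UC replicate 2, with the highest liver level of all samples (12.18), also had the highest Fasn signal (54610.4), and without it the lipogenesis median was 0.31 (camera adjusted p = 0.00866). The mean lipogenesis score was 0.37 ± 0.19 (SE) higher in UC than in CC, and 0.17 ± 0.22 with the liver level as a covariate. In UC replicates 3 and 5, whose liver levels were 8.51 and 8.21, Fasn was at 37705 and 39272. The median of the list against CC was 0.24 in these 2 samples and 0.37 in the 3 others. The 2 samples differed, with a mean lipogenesis score against the CC mean of 0.45 in UC replicate 3 and -0.02 in UC replicate 5. Single CC samples ran from -0.36 to 0.28. The liver level was also higher in UU than in CC, at 8.72 ± 0.14 (SD), with each of the 4 UU samples above the highest CC sample (exact permutation test, two-sided, p = 0.00794), and there the lipogenesis median was 0.08 (camera adjusted p = 0.933).

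The heat shock list was also higher in UC (12 of 14 members above 0, median 0.22, camera adjusted p = 0.00694, adjusted p = 0.524 with an estimated correlation). This was not particular to UC. Against the CC mean, the list's mean score ran from 0.16 to 0.34 in the UC samples and from 0.14 to 0.45 in the UU samples. The list was not called in UU against CC. Of its chaperones, Hspa8 had a log2 difference of 0.39 ± 0.13 and Hsph1 one of 0.63 ± 0.23. The 3 dimmer Hspa8 probe sets gave -0.25, -0.15 and -0.05. With a gene's probe sets averaged the list's median was -0.03 (adjusted p = 0.792), and with every probe set tested on its own 0.03 (adjusted p = 0.426). Immediate early genes, which respond within minutes to stimulation, were lower in UC (16 of 19 members below 0, median -0.37, camera adjusted p = 0.000167, adjusted p = 0.524 with an estimated correlation), with log2 differences of -1.03 ± 0.26 for Ier2, -0.65 ± 0.23 for the phosphatase Dusp1 and -0.48 ± 0.16 for the nuclear receptor Nr4a1. Without the 4 samples low in epididymal markers none of these 3 lists was called, with medians of 0.29 for lipogenesis (adjusted p = 0.349), 0.21 for heat shock (adjusted p = 0.349) and -0.26 for immediate early genes (adjusted p = 0.156). Within those 4 samples, 2 of each group, the lipogenesis median was 0.66, and within the 6 others of CC and UC, 3 of each group, it was 0.29. The 3'/5' ratio was on average 0.51 higher in UC than in CC on the log2 scale (exact permutation test, two-sided, p = 0.0794). With this ratio as a covariate the immediate early median was -0.17 (adjusted p = 7.04e-05), closer to 0.

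Gene by gene, limma called 0 genes higher and 0 lower in UC than in CC (smallest adjusted p = 0.381). At an unadjusted p under 0.05 there were 651 genes, against 371.8 expected by chance. Across alternative fits of 7436 genes this number ran from 356 with the 3'/5' ratio as a covariate to 1090 with array weights. It was 404 without UC replicate 4. The count of called genes was 0 in every alternative fit, also at an adjusted p under 0.1. The genes of smallest p are given as values. On the higher side, Cdkn1a, the cell cycle inhibitor p21, had a log2 difference of 1.08 ± 0.22, Trub2 of 0.89 ± 0.19, the glutathione transferase gene Gsta3 of 0.86 ± 0.17 and Emc6, of the ER membrane protein complex, of 0.69 ± 0.16. Dimmer probe sets gave -0.13 for Gsta3, -0.08 for Cdkn1a, 0.69 and 0.12 for Trub2 and 0.40 for Emc6. On the lower side were Net1, a guanine nucleotide exchange factor (-1.42 ± 0.31), Gpr108 (-0.93 ± 0.20), the secreted glutathione peroxidase gene Gpx3 (-0.87 ± 0.21), the transcriptional coregulator gene Cited2 (-0.76 ± 0.18) and Cnot3, of the CCR4-NOT deadenylase complex (-0.75 ± 0.16). Of the adipocyte genes in the panel, Adipoq (0.09 ± 0.23), Pparg (-0.09 ± 0.28) and Cebpa (0.03 ± 0.24) lay near 0. Lep, the leptin gene, gave 1.10 and was not called, with overlapping signals of 2746.9 to 10199.8 in CC and 8007 to 15556.4 in UC.

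UU against CC asks what undernutrition through both periods does to the depot. UU fat had lower levels of macrophage, matrix and endothelial transcripts and of genes of adipocyte fuel metabolism, and higher levels of general epithelial markers (21 of 22 members above 0, median 0.93). Of the 27 macrophage markers tested, 25 were below 0 (median log2 difference -0.90, camera adjusted p = 8.53e-13, adjusted p = 0.599 with an estimated correlation), and 16 were lower when adjusted over the list alone. Retnla, a secreted product of alternatively activated macrophages, had a signal of 5162 ± 3133 in UU (SD, n = 4) and 25359 ± 14255 in CC (n = 5), a log2 difference of -2.29 ± 0.42 (limma adjusted p = 0.0932). The mannose receptor gene Mrc1 was at 3877 ± 843 against 7821 ± 1802 and Lyz2, a macrophage lysozyme with a near-identical copy in Lyz1, gave a log2 difference of -1.82 ± 0.48. Collagens and other matrix genes were lower as a list (37 of 43 below 0, median -0.48, camera adjusted p = 9.77e-11, adjusted p = 0.599 with an estimated correlation, 17 lower when adjusted over the list alone). Fibronectin, Fn1, was at 10363 ± 1651 against 28505 ± 12198 (log2 difference -1.37 ± 0.30), with -0.77 ± 0.16 for Col6a3 and -0.83 ± 0.24 for Loxl1. The endothelial list was lower too (19 of 21 below 0, median -0.45, camera adjusted p = 1.74e-05, adjusted p = 0.599 with an estimated correlation), with -1.15 ± 0.34 for von Willebrand factor, Vwf, and -0.94 ± 0.31 for Pecam1. Without the 4 samples low in epididymal markers these lists were still called, with smaller medians of -0.59 for macrophage markers, -0.26 for matrix genes and -0.24 for endothelial markers. The endothelial median was -0.29 without CC replicate 4.

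A set of 6 adipocyte metabolism lists were lower in UU by camera. The lipolysis and lipid droplet list had 11 of 12 members below 0 (median -0.56, adjusted p = 0.000732), with Cidec, a lipid droplet coat protein, at -1.25 ± 0.36, hormone-sensitive lipase, Lipe, at -1.11 ± 0.37, monoglyceride lipase, Mgll, at -0.90 ± 0.24 and Plin4 at -0.75 ± 0.25. For fatty acid oxidation it was 19 of 24 (median -0.47, adjusted p = 0.000175), with -0.97 ± 0.33 for Etfdh and -0.72 ± 0.28 for Cpt2. A dimmer Cpt2 probe set gave 0.31. Glucose uptake and glycolysis had 17 of 23 below 0 (median -0.18, adjusted p = 0.00477), with -1.60 ± 0.36 for Pfkfb3, which makes the activator of phosphofructokinase, and -0.68 ± 0.16 for Pfkp. Dimmer probe sets gave -0.24 for Pfkfb3 and -1.44 for Pfkp. The TCA cycle had 19 of 22 below 0 (median -0.41, adjusted p = 0.00028), with -0.83 ± 0.25 for Sdhd and -0.72 ± 0.23 for Dld. A dimmer Sdhd probe set gave -0.11. Oxidative phosphorylation had 52 of 69 below 0 (median -0.19, adjusted p = 0.00028) with -0.70 ± 0.23 for Uqcrfs1, and branched-chain amino acid catabolism 16 of 18 (median -0.34, adjusted p = 0.00229). Adipokines and other secreted adipocyte products were lower as well (10 of 13 below 0, median -0.48, adjusted p = 0.00314), with -0.98 ± 0.25 for Ccdc80 and -0.77 ± 0.24 for Adipoq, the adiponectin gene. With an estimated correlation, the adjusted p of these 7 lists ran from 0.599 to 0.712. Without the 4 samples low in epididymal markers the 6 metabolism lists were not called and their medians lay closer to 0. They were -0.23 for lipolysis and lipid droplet (adjusted p = 0.0575), -0.20 for fatty acid oxidation (adjusted p = 0.0726), -0.10 for glycolysis (adjusted p = 0.0575), -0.16 for the TCA cycle (adjusted p = 0.121), -0.08 for oxidative phosphorylation (adjusted p = 0.201) and -0.16 for branched-chain amino acids (adjusted p = 0.125). Without CC replicate 2 alone the TCA cycle gave -0.21 (adjusted p = 0.0528) and oxidative phosphorylation -0.11 (adjusted p = 0.125). CC replicate 2 also carried Xist and skeletal muscle transcripts. With the call kept, single samples left out gave medians of -0.37 for lipolysis and lipid droplet and -0.27 for fatty acid oxidation without CC replicate 2, -0.22 for adipokines without UU replicate 1, -0.09 for glycolysis, -0.26 for the TCA cycle, -0.06 for oxidative phosphorylation and -0.18 for branched-chain amino acids without UU replicate 3 and -0.33 for glycolysis without UU replicate 4. The adipokine list stayed called without the 4 samples, at -0.31 (adjusted p = 0.0452). Array weights also ended the call of glycolysis (-0.06, adjusted p = 0.0614), oxidative phosphorylation (-0.04, adjusted p = 0.106) and branched-chain amino acids (-0.16, adjusted p = 0.0614). So did the epididymal level and 3'/5' ratio as covariates for glycolysis (-0.13, adjusted p = 0.118) and oxidative phosphorylation (-0.04, adjusted p = 0.0787), which was lost without the 2 samples with Xist signal too (-0.11, adjusted p = 0.122).

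In UU, 2 lists were higher than in CC. General epithelial markers, carried by epididymal epithelium among others, had 21 of 22 members above 0 (median 0.93, camera adjusted p = 0.000379, adjusted p = 0.655 with an estimated correlation), with 1.57 ± 0.79 for Cd24a and 0.83 ± 0.39 for the tight junction gene Cldn4. Without the 4 samples low in epididymal markers this median was 0.10 (adjusted p = 0.355), and without CC replicate 2 alone it was 0.44, still called. Cell cycle genes had 27 of 31 above 0 (median 0.24, camera adjusted p = 0.00807, adjusted p = 0.682 with an estimated correlation), among them Prim1 (0.77 ± 0.23) and Mcm6 (0.56 ± 0.19) of DNA replication, and the median was 0.15 (adjusted p = 0.238) without those 4 samples, 0.14 (adjusted p = 0.124) without CC replicate 4 and 0.11 (adjusted p = 0.106) without UU replicate 2. With the call kept, it was 0.38 without UU replicate 1 and 0.16 without UU replicate 3. It was 0.16 (adjusted p = 0.0542) with the epididymal marker level as a covariate. Dimmer probe sets gave 0.16 for Prim1 and 0.52 for Mcm6. De novo lipogenesis was not called (median 0.08, camera adjusted p = 0.933, adjusted p = 0.995 with an estimated correlation, 11 members above 0 and 9 below).

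No single gene passed in UU against CC by limma (0 higher, 0 lower, smallest adjusted p = 0.0532). There were 1218 genes at an unadjusted p under 0.05, against 371.8 expected by chance. Across alternative fits of 7436 genes this number ran from 776 without UU replicate 3 to 1340 without UC replicate 5. With the 3'/5' ratio as a covariate it was 866. Of called genes, array weights in the same fit gave 4 higher and 8 lower. Leaving out CC replicate 1 gave 1 higher and 1 lower, CC replicate 2 gave 0 and 1, and UU replicate 4 gave 1 and 2. Among the genes of smallest p, Mest, an imprinted gene whose level in fat follows adipose expansion, had a signal of 3444 ± 1435 in UU and 17848 ± 9437 in CC, a log2 difference of -2.26 ± 0.38 (adjusted p = 0.0583). H1f2, a linker histone gene, gave -0.98 ± 0.15 (adjusted p = 0.0532), where the dimmest of its 3 probe sets gave 0.46. The matrix protein gene Prelp gave -1.72 ± 0.32 and Itgb1bp1, an integrin-binding protein gene, -1.35 ± 0.26. The higher side held Med20 of the Mediator complex (1.36 ± 0.27), the chemokine Cxcl14 (1.07 ± 0.21), Rbm15 (0.92 ± 0.16), Qtrt2 of tRNA queuosine modification (0.91 ± 0.15) and the splicing factor Sf3a2 (0.73 ± 0.15). Dimmer probe sets gave 0.29 for Med20, 0.77 for Cxcl14, 0.48 for Qtrt2 and 0.12 for Sf3a2. Of the fixed panel, Cebpa gave -1.06 ± 0.25 (adjusted p = 0.124) and Pparg -1.01 ± 0.29 (adjusted p = 0.145). The list of adipogenic transcription factors was not called, and its mean score against the CC mean ran from -0.42 to -0.07 in the UU samples. Dgat2, which catalyses the last step of triglyceride synthesis, gave -1.36 ± 0.41. Leptin, Lep, gave -1.53 ± 0.82, and -0.22 without UU replicate 1, where its signal was 85.6.

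UC against UU sets ample against restricted nursing after the same restriction in utero. Here limma called 51 genes higher and 9 lower in UC (adjusted p under 0.05 of 7436 genes, 1332 at an unadjusted p under 0.05). Centring each array on its median, which moved the median of all genes from -0.06 to 0.08 on the log2 scale, gave 103 higher and 2 lower. Serpina1b, an alpha-1-antitrypsin gene expressed in liver as well, rose by 3.84 ± 0.78 on the log2 scale, from 1232 ± 965 in UU (SD, n = 4) to 10525 ± 2437 in UC (n = 5, adjusted p = 0.0343). UU replicate 1 had a signal of 36.2, and without it the log2 difference was 2.70 (adjusted p = 0.0933). Its probe sets can bind near-identical Serpina1 copies, so the copy is uncertain. Retnla rose by 2.72 ± 0.42 on the log2 scale (adjusted p = 0.0283), Rnase2a, an eosinophil-associated ribonuclease of a family of close copies, by 2.64 ± 0.50 and the chemokine Ccl6 by 2.37 ± 0.50. Mest rose by 2.32 ± 0.38 on the log2 scale, from 3444 ± 1435 to 16357 ± 2589 (adjusted p = 0.0283), Npr3, the natriuretic peptide clearance receptor, 3.75-fold, Dgat2 3.56-fold and Dtx2 3.16-fold.

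The falls included regulators of the circadian clock. Ier2, an immediate early gene, fell by 1.28 on the log2 scale, the clock repressor Nr1d2 by 1.19 (from 4824 ± 959.9 in UU to 2109 ± 512 in UC, adjusted p = 0.0343), Per3, a period gene, by 1.16 and Glo1, a glyoxalase that removes methylglyoxal, by 1.13. Slf2 fell by 1.04, Cxcl14 by 0.99, Obsl1 by 0.85 and Ccnt2, a cyclin of transcription elongation, by 0.76, though a dimmer Ccnt2 probe set gave 0.12. The circadian clock list was lower in UC (10 of 12 members below 0, median -0.78, camera adjusted p = 0.000736, adjusted p = 0.545 with an estimated correlation), with 2 members lower over all genes and 8 lower and 2 higher when adjusted over the list alone. Tef, a clock output factor, gave -0.76 ± 0.19 (adjusted p = 0.0731). The list's call ended when a gene's probe sets were averaged (median -0.59, adjusted p = 0.0827) and when the dimmest 60% of genes were left out (median -0.76, adjusted p = 0.36).

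**Figure D2:**
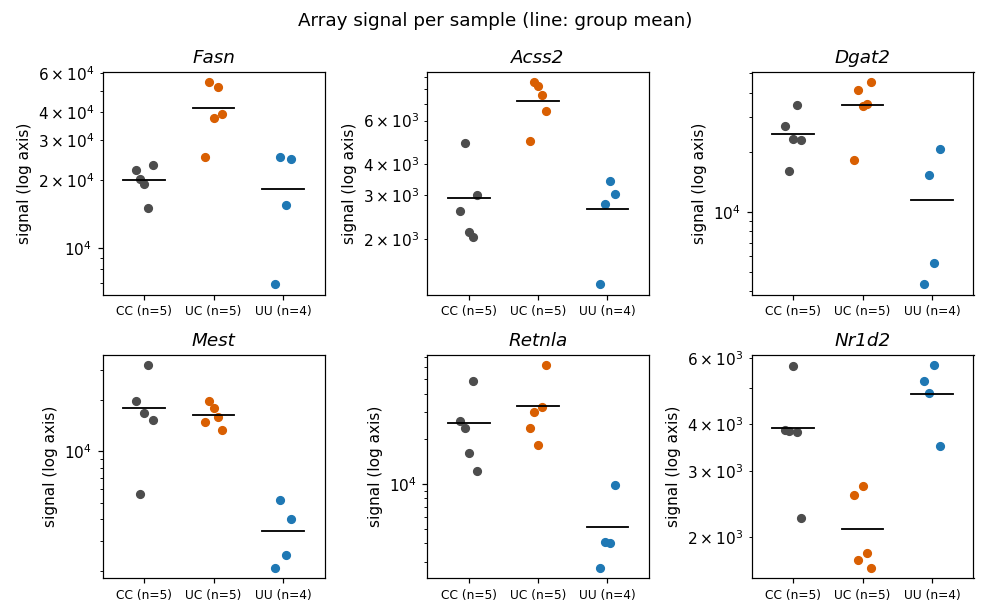
Array signal (log axis) of 6 named genes in each sample, by group, with a line at the group mean (n = 5 for CC and UC, n = 4 for UU). Mest and Retnla have their lowest group mean in UU (3444 and 5162), Acss2 and Fasn their highest in UC (7194 and 41823).

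Lipid synthesis genes were higher in UC than in UU. The de novo lipogenesis list had 13 members above and 7 below 0 (median 0.24, camera adjusted p = 0.00522, adjusted p = 0.545 with an estimated correlation), and without UU replicate 1 its median was 0.09 (adjusted p = 0.0548). With the call kept, the median was 0.13 without UC replicate 2, 0.13 without UC replicate 4 and 0.36 without UC replicate 5. The liver level was 0.84 higher in UC than in UU (exact permutation test, two-sided, p = 0.397). Without UC replicate 2 it was 8.90 ± 0.65 (SD) in UC, against 8.72 ± 0.14 in UU. The lipogenesis score was 0.29 ± 0.20 (SE) higher in UC than in UU, or 0.18 ± 0.20 with the liver level as a covariate. Acss2 was its 1 called member, up 2.82-fold by its log2 difference, with means of 2637 ± 920.2 in UU and 7194 ± 1461 in UC (adjusted p = 0.0343), and 5 were higher when adjusted over the list alone. Fasn gave 1.32 ± 0.33 (adjusted p = 0.0731), the malic enzyme Me1 1.24 ± 0.30, Thrsp 0.99 ± 0.36 and Pgd 0.71 ± 0.20, whereas Scd1 gave -0.05 ± 0.19, Elovl6 0.00 ± 0.23 and Gpam -0.01 ± 0.18. A dimmer Thrsp probe set gave 0.22. The cholesterol synthesis list was higher (12 of 17 above 0, median 0.14, camera adjusted p = 0.0146, adjusted p = 0.545 with an estimated correlation) with Hmgcs1, the HMG-CoA synthase, up 2.33-fold (adjusted p = 0.0283). That list's median was 0.09 without UC replicate 3 (adjusted p = 0.065) and 0.22 without UU replicate 1 (adjusted p = 0.055), and 0.05 with the replicate number as a block (adjusted p = 0.0507). With the call kept, it was 0.29 without UC replicate 1, 0.08 without UC replicate 5, 0.07 without UU replicate 3 and 0.23 without UU replicate 4.

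Lists of fuel use and adipocyte secretion were likewise higher in UC than in UU, while general epithelial markers were lower. The mean score difference was 0.66 ± 0.24 (SE) for lipolysis and lipid droplet and 0.42 ± 0.18 for the TCA cycle. With the general epithelial score as a covariate these were 0.31 ± 0.19 and 0.12 ± 0.11. The lipolysis and lipid droplet list had a median of 0.76 (10 of 12 above 0, camera adjusted p = 7.47e-05), with Mgll up 2.37-fold (adjusted p = 0.0343), 1.06 ± 0.36 for Cidec and 0.98 ± 0.25 for Plin4. Glucose uptake and glycolysis had a median of 0.34 (16 of 23, adjusted p = 0.000883) and 3 called genes, the phosphofructokinases Pfkl (1.11 ± 0.21) and Pfkp (0.77 ± 0.16) and lactate dehydrogenase Ldha (1.01 ± 0.20). Pfkfb3 gave 1.61 ± 0.36 (adjusted p = 0.0502), and a dimmer probe set of it gave -0.03. A dimmer Pfkl probe set gave 0.20. The TCA cycle list had a median of 0.51 (20 of 22, adjusted p = 2.90e-06), with 0.96 ± 0.24 for Idh3a. Oxidative phosphorylation had one of 0.29 (58 of 69, adjusted p = 1.31e-07), fatty acid oxidation one of 0.43 (20 of 24, adjusted p = 0.000391) and branched-chain amino acid catabolism one of 0.23 (12 of 18, adjusted p = 0.0334). Adipokines had a median of 0.43 (9 of 13, adjusted p = 0.000652), with 0.86 ± 0.24 for Adipoq and 2.63 ± 0.82 for Lep (adjusted p = 0.131). The Lep value was 1.32 without UU replicate 1. With an estimated correlation these lists had an adjusted p of 0.545, except branched-chain amino acids with 0.625. Without the 4 samples low in epididymal markers the medians were smaller, at 0.56 for lipolysis and lipid droplet, 0.20 for glycolysis, 0.26 for the TCA cycle, 0.14 for oxidative phosphorylation, 0.17 for fatty acid oxidation and 0.29 for adipokines, all still called. Leaving out single samples gave 0.28 for fatty acid oxidation without UC replicate 5 and 0.21 for glycolysis and 0.25 for adipokines without UU replicate 3, with the calls kept. Fatty acid oxidation was not called with the epididymal marker level as a covariate (0.18, adjusted p = 0.0541).

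In UC against UU, branched-chain amino acid catabolism kept its call in 22 of 33 alternatives. It was lost without UC replicate 2 (median 0.15, adjusted p = 0.126), UC replicate 5 (0.20, adjusted p = 0.18) or UU replicate 3 (0.16, adjusted p = 0.323). It was lost with the dimmest 60% of genes left out (0.23, adjusted p = 0.0897), median centring (0.36, adjusted p = 0.0567), quantile normalization (0.22, adjusted p = 0.0996) and array weights (0.13, adjusted p = 0.212). It was also lost without the 2 samples with Xist signal (0.20, adjusted p = 0.124) or the 4 low in epididymal markers (0.10, adjusted p = 0.58), and with the epididymal level as a covariate alone (0.09, adjusted p = 0.478) or with the 3'/5' ratio (0.10, adjusted p = 0.414).

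Macrophage, matrix and endothelial lists were higher in UC as well. Macrophage markers had a median of 0.83 (22 of 27 above 0, camera adjusted p = 3.03e-08, 10 higher when adjusted over the list alone), with a rise of 1.17 ± 0.21 for Mrc1, and collagens and extracellular matrix one of 0.36 (37 of 43, adjusted p = 2.20e-08), with rises of 1.16 ± 0.24 for Col5a3, 1.09 ± 0.24 for Loxl1 and 0.72 ± 0.16 for Col6a3. Endothelial markers had a median of 0.41 (18 of 21, adjusted p = 7.86e-05) with 1.36 ± 0.34 for Vwf. Without the 4 samples low in epididymal markers these 3 medians were 0.50, 0.25 and 0.30, all still called, but general epithelial markers were still lower in UC there (-0.59). The endothelial median was 0.27 without UC replicate 5. Interferon-stimulated genes had one of 0.38 (10 of 12, adjusted p = 0.0131) with 0.91 ± 0.24 for Lgals3bp, and 0.24 without UC replicate 5 (adjusted p = 0.15). With an estimated correlation the adjusted p of these 4 lists was 0.545. The interferon list also lost its call without the 2 samples with Xist signal (0.24, adjusted p = 0.122) or the 4 low in epididymal markers (0.25, adjusted p = 0.112), and with the epididymal level as a covariate alone (0.16, adjusted p = 0.135) or with the 3'/5' ratio (0.13, adjusted p = 0.159).

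Ribosomal protein genes and epithelial markers were lower in UC than in UU. Ribosomal protein genes were lower in UC (34 of 42 below 0, median -0.20, adjusted p = 0.015), with -0.89 ± 0.30 for Rps15, a call that ended without UC replicate 2 (-0.15, adjusted p = 0.0829), UC replicate 3 (-0.20, adjusted p = 0.0503) or UU replicate 1 (-0.12, adjusted p = 0.346). It also ended with no filter on dim genes (-0.20, adjusted p = 0.0662), without the 2 samples with Xist signal (-0.18, adjusted p = 0.0596), without the 4 low in epididymal markers (-0.12, adjusted p = 0.348) and with the epididymal level as a covariate (-0.16, adjusted p = 0.0802). General epithelial markers were lower in UC (22 of 22 below 0, median -1.31, adjusted p = 2.90e-06), with -2.05 ± 0.79 for Cd24a (-1.42 without UC replicate 5) and -1.56 ± 0.50 for Spint2, and so were epididymal markers (10 of 10, median -1.23, adjusted p = 0.0311). With an estimated correlation the adjusted p was 0.545 for general epithelial markers, 0.626 for ribosomal proteins and 0.626 for epididymal markers. The epididymal list lost its call without UC replicate 2 (-0.92), UC replicate 5 (-0.92), UU replicate 2 (-1.18), UU replicate 3 (-1.11) or UU replicate 4 (-1.20), with adjusted p from 0.0553 to 0.216. It was also lost without the 2 samples with Xist signal (-0.92, adjusted p = 0.215), without the 4 low in these markers (-0.02, adjusted p = 0.945) and with the 3'/5' ratio as a covariate (-1.26, adjusted p = 0.0505). General epithelial markers stayed called without those 4 samples, at -0.59.

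**Figure D3:**
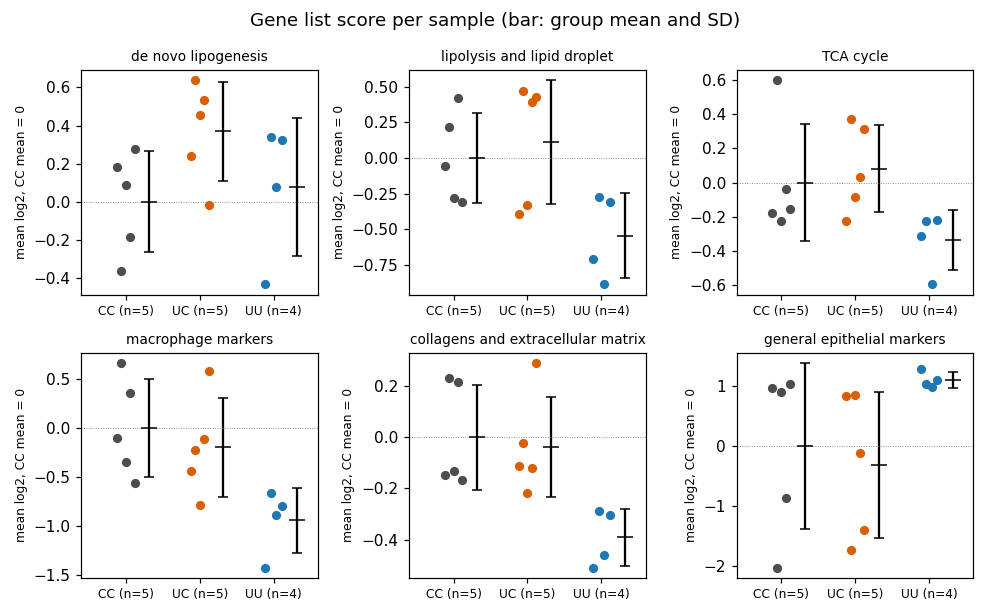
Mean log2 level of 6 gene lists in each sample, with the CC mean set to 0; the bar beside each group gives its mean and SD (n = 5 for CC and UC, n = 4 for UU). The UU samples lie lowest for collagens and extracellular matrix, and general epithelial markers spread widely in CC and UC.

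The count of 60 genes in UC against UU rested on single arrays. It was 0 without UC replicate 2, without UC replicate 4 or without UU replicate 1, 6 higher and 0 lower without UC replicate 5, 12 and 0 without UU replicate 2, 13 and 1 without CC replicate 1, 20 and 2 without UU replicate 4, 22 and 7 without UU replicate 3, 91 and 17 without UC replicate 1, and the 9 lower became 5 without CC replicate 3 or CC replicate 5 and 19 without UC replicate 3. It was 3 higher and 0 lower without the 2 samples with Xist signal, 1 and 0 without the 4 low in epididymal markers, and 1 and 1 without the 3 of highest 3'/5' ratio. In each of these fits all 60 genes kept their direction. This says little about how firm the calls are, because the genes were chosen for small p in arrays that these fits share.

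Both comparisons against CC used the same 5 CC samples. No gene was called in both, which was fixed because neither comparison called a gene, so it says nothing about shared or separate changes. In simulated unchanged groups the number was 0 in the median and at most 2. At an unadjusted p under 0.05 in both and in the same direction there were 140 genes, against a median of 20.5 in 100 simulations of unchanged groups sharing the controls (range 0 to 938), 53.6 for independent lists, and 35.5 (27 to 70) when each comparison had its own 2 or 3 CC samples in 20 divisions. Across genes, which are not independent replicates, the correlation of the log2 differences was 0.253 against a simulated median of 0.547 and 0.0623 with divided controls, and the covariance was 0.0318 against a simulated 0.0328.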

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

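All tests of explanations in this part were chosen after the result was seen. Samples were looked at gene by gene and list by list for one value far from the rest of its group. Of 402 groups examined, 39 held such a sample. The items included liver and sex-linked markers added after the data were seen, and items measured on the same arrays are not independent. The count therefore cannot be set against the 1 in 20 that chance gives for independent items. CC replicate 2 accounted for 13 of the 39 and UU replicate 3 for 8.

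Apart from the sex-linked genes, CC replicate 2 stood apart above its group for 6 genes, with 1701 for Net1 against 914 to 1093, 20521 for Pdk4 against 1018 to 2364, 2037 for Nr4a1 against 1362 to 1453, 5378 for Etfdh against 2016 to 2593, 6661 for Dld against 4044 to 4479.7 and 14876 for Uqcrfs1 against 8552 to 9867 in the other CC samples. Apart from those genes, it stood apart below its group for 3, with 8618 for Srebf1 against 12074 to 12760.2, 911 for Hsph1 against 2032 to 2479 and 196 for Cldn4 against 811 to 1038. Its TCA cycle list score was 0.67 against -0.16 to 0.03 on the log2 scale, with the mean of all arrays at 0. In CC replicate 4 the signal stood above the group with 100200 for Scd1 against 55863 to 64684, 5442 for Itgb1bp1 against 2947 to 3267 and 2853 for Pecam1 against 1606 to 1818, and in CC replicate 1 with 4766 for Glo1 against 2207 to 2479.

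UU replicate 3, the sample with the highest 3'/5' ratio of its group (log2 ratio 2.11 against 0.75 to 0.94), had the lowest UU signal for Adipoq (25263 against 43471 to 45790.2), Sdhd (1839 against 2979 to 3017), Dld (1924 against 3050.5 to 3308) and Pfkp (749 against 1034 to 1101), the highest for Glo1 (7200.3 against 4987 to 5052), and a score of the branched-chain amino acid catabolism list of -0.50 against -0.10 to -0.04. Leptin was at 85.6 against 3768 to 5948 in UU replicate 1. The mean log2 level of liver markers was 8.50 against 8.78 to 8.81 in UU replicate 2. In UC, Adipoq was at 43138 against 71952 to 87601 in replicate 3, Ier2 at 545 against 379.5 to 394 in replicate 4, Serpina1b at 6434 against 10708 to 12551 in replicate 1 and Rnase2a at 17038 against 3594 to 5009.6 in replicate 5. Of the clock genes, Arntl was at 1462 against 1021 to 1060.5 in UU replicate 3, Clock at 1328 against 1583 to 1697 in CC replicate 5 and Npas2 at 137 against 603 to 835 in UC replicate 5. The liver transcript Serpina1c was at 15702 against 1086 to 2023 in UC replicate 2 and 602 against 893 to 936 in UU replicate 4.

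Xist RNA was present in 2 samples labelled male. CC replicate 2 had an Xist signal of 3981 against 588 to 955 in its group, Eif2s3y of 58.6 against 1235 to 2143 and the Y-linked Uty of 119 against 1486 to 2009.8; UC replicate 5 had Xist at 5642 against 481 to 859.7, Eif2s3y at 7.9 against 1302 to 2146, Uty at 137 against 1859 to 2174 and Kdm5d at 339.5 against 1095 to 1449. A mix of male and female tissue would leave Y-linked transcripts at an intermediate level, and tissue of female mice under male labels would leave them near background. As a share of the lowest value among the other 12 samples, Eif2s3y and Uty reached 4.75% and 8.03% in CC replicate 2. In UC replicate 5 they reached 0.64% and 9.25%, but Kdm5d reached 21% in CC replicate 2 and 47.4% in UC replicate 5. A mix would leave all these genes at similar shares. Eif2s3y and Uty thus argue against a male share as large as Kdm5d gives. A small male share and female tissue cannot be told apart. Female tissue also needs low epididymal transcripts, and the log2 ratio of the higher Gpx5 signal of these samples to the lowest of the 10 samples with epididymal markers was -2.31. CC replicate 4 and UC replicate 2 were as low in Gpx5 with Eif2s3y in the range of the other samples, so low Gpx5 alone does not mark a female, and no biological explanation was tested.

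The second pattern is the higher adipocyte, macrophage and matrix lists in UC than in UU, with differences of the mean list score of 0.66 ± 0.24 (SE) for lipolysis and lipid droplet, 0.42 ± 0.18 for the TCA cycle, 0.75 ± 0.31 for macrophage markers and 0.35 ± 0.12 for matrix genes. More epididymal or other epithelial tissue in UU would dilute all of them, and it cannot be told apart from a group effect. In the 10 samples with epididymal markers the differences were 0.44 ± 0.24, 0.25 ± 0.10, 0.50 ± 0.24 and 0.24 ± 0.06 in the same order, but while epididymal markers differed there by -0.02 ± 0.34, general epithelial markers were still lower in UC (-0.58 ± 0.24). With the general epithelial score as a covariate in all 14 samples they were 0.31 ± 0.19, 0.12 ± 0.11, 0.28 ± 0.23 and 0.17 ± 0.08, none of them 2 SE from 0, and with this covariate in the 10 samples alone they were 0.01 ± 0.24, 0.17 ± 0.15, 0.11 ± 0.26 and 0.19 ± 0.08, of which matrix genes alone lay over 2 SE from 0. With the 3'/5' ratio as a covariate the differences were 0.68 ± 0.24, 0.43 ± 0.19, 0.75 ± 0.33 and 0.36 ± 0.13. The mean log2 ratio differed by only 0.07 between UC and UU, so this covariate could hardly move them and decides little about RNA integrity. Without the 3 samples of highest ratio they were 0.62 ± 0.28, 0.45 ± 0.22, 0.82 ± 0.44 and 0.38 ± 0.17. Those samples were thus not their whole source, though macrophage markers then lay under 2 SE from 0. An effect of nursing stays open beside the mix of tissues.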

How the results depend on the processing

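The fits without the samples with Xist signal, low epididymal markers or high 3'/5' ratio, and those with covariates, were chosen after seeing the data; the other alternatives were planned. In UC against CC the count of genes stayed at 0 in every alternative, including an adjusted p of 0.1. No gene could therefore be called in both comparisons with CC in any of them. UU against CC (0 higher, 0 lower) gave 0 higher and 1 lower with no filter on dim genes, 1 higher and 2 lower with the dimmest 60% left out, 4 higher and 8 lower with array weights, 5 higher and 6 lower at an adjusted p of 0.1, 0 higher and 1 lower without the 2 samples with Xist signal, 0 higher and 1 lower without the 4 low in epididymal markers, 7 higher and 9 lower with the epididymal marker level as covariate, 0 higher and 1 lower with the 3'/5' ratio and 4 higher and 7 lower with both; leaving out 1 array gave 0 to 1 higher and 0 to 2 lower. UC against UU (51 higher, 9 lower) gave 23 higher and 2 lower with no filter, 64 and 5 with the dimmest 60% left out, 103 and 2 with median centring, 36 and 4 with a gene's probe sets averaged, 7 and 2 in a fit of the 2 groups alone, and 151 and 48 at an adjusted p of 0.1. It gave 3 and 0 without the 2 samples with Xist signal, 1 and 0 without the 4 low in epididymal markers, 1 and 1 without the 3 of highest 3'/5' ratio, 14 and 1 with the epididymal level as covariate, 92 and 23 with the 3'/5' ratio and 81 and 27 with both, and leaving out 1 array gave 0 to 91 higher and 0 to 19 lower. The cause was not tested. The de novo lipogenesis median of 0.30 in UC against CC lost its call with an estimated correlation (adjusted p = 0.845), with fry (adjusted p = 0.46) and without the 4 samples low in epididymal markers (0.29, adjusted p = 0.349), and ran from 0.24 to 0.35 with 1 array left out. The 0.24 of UC against UU lost its call with an estimated correlation (adjusted p = 0.545) and with fry (adjusted p = 0.256), and ran from 0.09 to 0.36, the lowest without UU replicate 1 (0.0898, adjusted p = 0.0548). In UU against CC it ran from -0.02 to 0.29 and was never called. Of the other list results, 1 turned: the epididymal marker list in UU against CC, not called with all samples (median 0.92), was -0.89 (adjusted p = 0.00848) without the 4 samples low in those markers, which were all CC or UC samples. Outside the estimated correlation and fry, 13 of 32 called lists kept their call in all 33 alternatives.

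The labels give the 3 groups the same replicate numbers but name no pairing. Of 13 same-numbered pairs, 6 had deviations from their group means that correlated over 0.1 (range -0.32 to 0.49). The median correlation was 0.07 in these pairs and -0.03 in the others, and 3 of 14 samples correlated best with their own number. The mix of tissues also enters these correlations, so they do not settle whether the samples were paired. With the number as a replicate block, UU against CC gave 1 higher and 6 lower and UC against UU 79 higher and 15 lower. Detection calls were not used here, so whether a dim transcript was above background was not judged, and the filter on dim genes stood in for it.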

Other observations

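The tests of clock genes in this part were chosen after the values were seen; the splits of the samples were planned. Imprinted genes that act on growth lay on both sides of 0. The list's 15 tested members had a median of -0.19 in UU against CC (10 below 0, camera adjusted p = 0.0812) and of -0.02 in UC against CC (adjusted p = 0.762). Mest had a log2 difference of -2.26, whereas Dlk1, a preadipocyte gene whose loss goes with adipocyte maturation, gave 1.06 ± 0.39 (adjusted p = 0.212) and Igf2, a fetal growth factor, 0.66 ± 0.25 (adjusted p = 0.213) in the same comparison, named after their values were seen. Sgce, the neighbour of Peg10 in its imprinted cluster, gave -0.53 ± 0.17.

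Skeletal muscle transcripts were abundant in 2 of the CC samples. Acta1, skeletal actin, was at 7453 in CC replicate 2 and 9065 in CC replicate 5, against 25.4 to 873 elsewhere, and Myh4, a fast myosin, at 2102 and 1416 against 16.5 to 209. The liver transcripts of UC replicate 2 included Ttr at 32323 and Serpina1c at 15702. Ttr was also at 6491 and 5663 in UC replicates 1 and 4, and at no more than 1228 in the other 11 samples.

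Clock genes differed in opposite directions between UC and UU. Arntl, the partner of Clock, gave 0.71 ± 0.19 and Clock 0.59 ± 0.18 in UC against UU, while Dbp gave -1.29 ± 0.38 and Nr1d2 and Per3 fell. Npas2, which was placed beside Arntl and Clock, gave -0.73 ± 0.38. The mean of these 3 minus the mean of the 9 other tested clock genes was 0.37 ± 0.46 (SD) in UC and -0.77 ± 0.22 in UU, a difference of 1.14. Against CC it was 0.80 for UC and -0.34 for UU. The score was built after several of its genes had been seen to part UC from UU, so no p is given for it. The difference was 1.07 ± 0.25 (SE) in the 10 samples with epididymal markers and 0.88 ± 0.28 with the general epithelial score as a covariate. The SE does not cover the choice of genes, so these values do not decide whether more epididymal or other epithelial tissue in UU was the whole cause. A different hour or feeding phase at tissue collection and an effect of nursing cannot be told apart for the value of 1.14, because the labels give no collection time.

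Samples were also divided anew between each pair of groups, with the third group kept. For UC against UU, 1 of 100 splits, the real one, gave as many as 60 genes, and the highest of the others gave 49. Under 5% of the splits tried thus reached the real count. The splits treat each array as an independent animal, so shared litters or the mix of tissues are not excluded. With a real count of 0, any split gives as many, so the 100 of 100 for UC against CC and the 100 of 100 for UU against CC decide nothing about chance. The highest of the others gave 77 genes for UC against CC and 1 for UU against CC. The split with 77 genes set CC replicates 3 and 5 and UC replicates 1, 3 and 4 against the rest. It put all 4 samples low in epididymal markers on one side. Whether that structure of the samples gave the count was not tested.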
